A study of Homo sapiens with 30 samples.

How the data were processed

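Messenger RNA was measured in 30 libraries of HEK293 cells, an established human embryonic kidney line. Per the labels' protocols, cells were transfected with a plasmid for an EGFP(mutant)-mCherry mistranslation reporter, alone or carrying also the cognate missense-correcting tRNA (mc-tRNA), a tRNA engineered to be charged with an amino acid other than the one its anticodon stands for. Also per the labels' protocols, mCherry-positive cells were sorted 48 h after transfection, total RNA was selected for polyA, and strand-specific TruSeq libraries were sequenced on a NovaSeq6000. The labels' protocols describe the 3 libraries of each of the 10 groups as independent replicates, so the p-values below measure the spread between such replicates.

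Per the submitters' processing notes, the authors used STAR, SAMtools and featureCounts with genome build hg38; tool versions, the gene annotation and the value of the strand option are not given in the sources used here. The deposited values are raw counts per gene, 1 file per library, with no normalization. Each file listed 58370 features: 58278 Ensembl genes with versioned identifiers and 92 ERCC spike-in sequences. Of the gene identifiers, 55109 were present with the same version in GENCODE release 29, from which positions (GRCh38) were taken. Symbols came from a symbol table for 41844 genes and from GENCODE release 29 for 999 others. Gene totals were 39017548 to 55446962 counts per library. A count of 0 allows up to 3 counts, which is 0.0541 to 0.0769 CPM (counts scaled to the library total) depending on the library; intervals and floors cover counting error only. The ERCC counts entered no test. A chi-square test of the counts of each pair of replicates, over genes with at least 10 counts, gave 2.08 to 36.7 per degree of freedom in the 30 pairs, so replicates differed by more than counting error and the fit below estimates that extra spread.

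Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit, TMM factors, low counts removed by filterByExpr, robust dispersion), with 10 group means over all 30 libraries and 20 residual degrees of freedom; 22321 genes were tested and the biological coefficient of variation was 8.24%. A gene is called, and said to have risen or fallen, when its Benjamini-Hochberg adjusted p is under 0.05; adjusted p-values are from edgeR unless another tool is named. There were 8 tests across all genes: each mc-tRNA against its reporter alone (5), the mean of these 5 effects, an F-test of whether the effects differ, and an F-test among the 5 reporters without mc-tRNA. Each of the 10 pairs of effects was also tested for a difference. Changes are log2 fold changes ± SE of 3 libraries with the mc-tRNA against 3 with the reporter alone, and CPM values are means ± SD of 3 libraries. Outside the floors and the filters on low counts, CPM is scaled to the library total multiplied by its TMM factor. The fit was tested on simulated data with known changes: for the EGFP(R96Q) comparison, 16.3% of 49 genes changed 1.25-fold, 53.2% of 47 changed 1.5-fold, 64% of 50 changed 2-fold and 93.8% of 48 changed 4-fold were recovered, and 0 to 5 of the unchanged genes were called in the 8 tests. The simulation drew genes independently, with the same mean in all groups except for the changed genes in the Arg-tRNA_Gln(CUG) group. It lacked the large differences between groups seen in the real libraries, so these rates may not carry over to them.

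The design, the 23 gene lists and the rule for naming genes were fixed before the data were examined. The lists were cytosolic chaperones and heat shock genes, the ER unfolded protein response, integrated stress response (ATF4) targets, cytosolic and mitochondrial aminoacyl-tRNA synthetases, 26S proteasome subunits, cytosolic ribosomal proteins, p53 targets, interferon-stimulated genes, NF-kB and inflammatory genes, immediate early genes, NRF2 oxidative stress targets, RNA polymerase III and its factors, tRNA processing and modification enzymes, ribosome quality control and ribotoxic stress, translation initiation and elongation factors, cholesterol synthesis, autophagy, cell cycle, hypoxia and glycolysis, mitochondrially encoded mRNAs, replication-dependent histones, and markers of other cell types (stromal, blood, keratinocyte). Lists were tested with camera of limma 3.58.1 (log2 CPM with a prior count of 2, preset inter-gene correlation of 0.01), adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Camera asks whether a list moves more than the other genes, fry whether its members move on balance in either direction. With the estimated correlation, the calls that hold are 2 lists for Arg-tRNA_Cys(GCA), 7 for Arg-tRNA_His(GUG), 6 for Arg-tRNA_Trp(CCA), 2 for the mean effect, and 0 for Ser-tRNA_Arg(CCG) and for Arg-tRNA_Gln(CUG), each named with its p in the results.

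Genes are named by the following rule. In each comparison these are the 10 largest rises and 10 largest falls among called genes with a symbol, a mean of at least 1 CPM and no overlap between the groups (for the mean effect, the same sign in all 5 comparisons); the 4 members with the smallest p of each called list; and 7 fixed stress genes (HSPA1A, HSPA5, DDIT3, ASNS, ATF3, IFIT1 and CDKN1A). For each F-test it is the 10 genes with the smallest p. Any other gene is said to be chosen after its values were seen.

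Alternatives tried were RLE factors, no filter or a filter of 1 CPM in 3 libraries, the replicate number as a block, limma voom with quality weights, DESeq2 1.42.0, only the 6 libraries compared, an adjusted p under 0.01, and leaving out each library in turn. Scaling by library totals alone and leaving out the 6 EGFP(R65) libraries were added after seeing the data. Besides the estimated correlation and fry, the gene lists were retested only with RLE factors, library totals and the replicate block. The replicate numbers were not used as a block in the fit, as the labels do not say that they pair libraries. Residual correlations between libraries of the same number in a comparison were -0.0772 to 0.140, and 9 of 15 libraries resembled their own number most, where chance gives 5, so some pairing is not ruled out. With the block 231 genes were called with Arg-tRNA_Gln(CUG) in place of 123, and 1124 with Arg-tRNA_His(GUG) in place of 560. Counts of reads for transgenes, and tRNA levels, were not analysed here.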

Results

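Gene-level mRNA counts were available for 30 libraries of HEK293 cells in 10 groups of 3. For each of 5 mistranslation reporters, EGFP(R65), EGFP(R96Q), EGFP(R96C), EGFP(R96H) and EGFP(R96W), 1 group received the reporter alone and 1 received it with its cognate mc-tRNA on the same plasmid. These were Ser-tRNA_Arg(CCG), Arg-tRNA_Gln(CUG), Arg-tRNA_Cys(GCA), Arg-tRNA_His(GUG) and Arg-tRNA_Trp(CCA), in that order. The series asks how mc-tRNAs affect mRNA levels, which each comparison of a reporter with and without its mc-tRNA addresses.

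The first principal component of log2 CPM took 41.9% of the variance. It set the 6 EGFP(R65) libraries, at -145.7 to -94.4, apart from the 24 EGFP(R96) libraries, at -9.34 to 53.1. The second took 19.7% and was highest, at 118.1 to 123.2, in the libraries with Arg-tRNA_Cys(GCA). All 6 EGFP(R65) libraries had 0 ERCC counts and the 24 EGFP(R96) libraries had 10 to 106. Each mc-tRNA is compared within its own reporter, but all 30 libraries share 1 fit. Without the EGFP(R65) libraries, an alternative chosen after seeing the data, 369 genes in place of 560 were called with Arg-tRNA_His(GUG) and 95 in place of 123 with Arg-tRNA_Gln(CUG). In a comparison of EGFP(R65) with the other reporters, the reporter and a possible batch cannot be told apart.

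**Figure D1:**
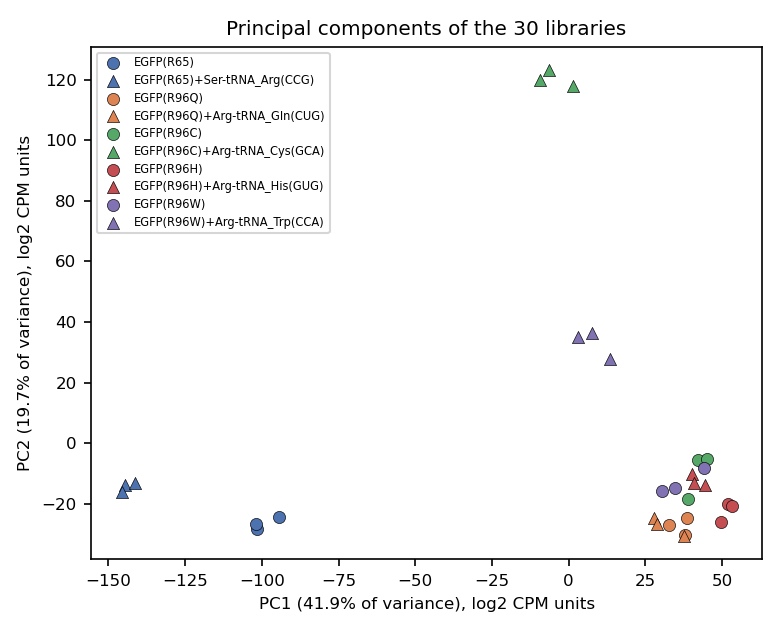
Principal components of log2 CPM, PC1 (41.9% of the variance) on the x axis and PC2 (19.7%) on the y axis; each point is 1 of 30 libraries, circles are reporter alone and triangles are with the mc-tRNA. The 6 EGFP(R65) libraries lie at -94.4 or below on PC1, and the 3 libraries with Arg-tRNA_Cys(GCA) at 118.1 or above on PC2.

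The number of called genes ranged from 123 of 22321 with Arg-tRNA_Gln(CUG) to 13550 with Arg-tRNA_Cys(GCA). It was 560 with Arg-tRNA_His(GUG), 9480 with Arg-tRNA_Trp(CCA) and 12790 with Ser-tRNA_Arg(CCG). The 2 groups did not overlap for 66.3% of the tested genes with Ser-tRNA_Arg(CCG), 16.2% with Arg-tRNA_Gln(CUG), 61.8% with Arg-tRNA_Cys(GCA), 27.0% with Arg-tRNA_His(GUG) and 47.8% with Arg-tRNA_Trp(CCA), where chance gives 10%.

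**Figure D2:**
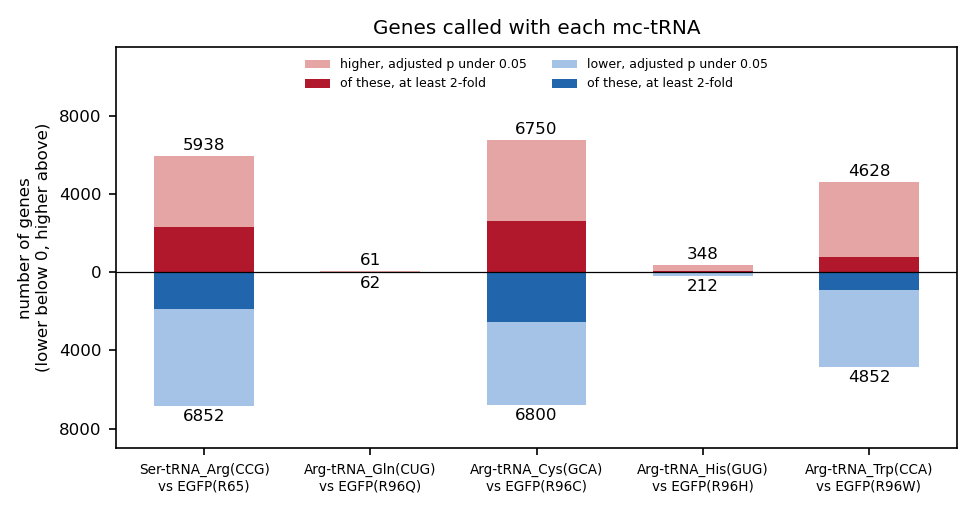
Number of genes called at an adjusted p under 0.05 (y axis, higher above 0 and lower below) for each mc-tRNA against its reporter alone (x axis, 3 libraries a group); the darker part of each bar is the genes changed at least 2-fold. The counts run from 61 higher and 62 lower with Arg-tRNA_Gln(CUG) to 6750 higher and 6800 lower with Arg-tRNA_Cys(GCA), where library totals in place of TMM give 3143 higher and 12401 lower.

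With Ser-tRNA_Arg(CCG), 5938 genes rose and 6852 fell, of which 2316 and 1865 changed at least 2-fold. Genes of the ER unfolded protein response rose together: 27 of 28 rose and 1 fell, the same adjusted over the list alone, with a median log2 change of 0.99. The unfolded protein response list had a camera adjusted p of 4.38e-16, and an adjusted p of 0.116 with an estimated correlation. HSPA5, the main ER chaperone (ENSG00000044574, chromosome 9, 125234853 to 125241330), rose by 1.69 ± 0.07, from 588 ± 22.7 to 1899 ± 123 CPM. PDIA4, an ER protein disulfide isomerase (ENSG00000155660, chromosome 7, 149003062 to 149028641), rose by 2.64 ± 0.07, and HSP90B1 and CRELD2, also of the ER, rose by 1.59 ± 0.07 and 1.54 ± 0.07. Among replication-dependent histones 14 of 21 rose, the same adjusted over the list alone, with H2BC12 at 1.82 ± 0.08, H2BC5 at 2.85 ± 0.15 and the linker histone H1-2 at 2.38 ± 0.11. The RNA was selected for polyA, so histone counts here and below cover polyA RNA only, not total histone mRNA. The histone list had a camera adjusted p of 2.23e-06, and an adjusted p of 0.162 with an estimated correlation. Among integrated stress response targets 4 of 36 rose and 21 fell, the same adjusted over the list alone, with the tRNA exportin XPOT at -1.02 ± 0.07, the transcription factor CEBPG at -1.32 ± 0.10 and the serine synthesis enzyme PSAT1 at -0.75 ± 0.08. The integrated stress response list had a camera adjusted p of 0.00861, and an adjusted p of 0.671 with an estimated correlation.

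Among cytosolic ribosomal protein genes with Ser-tRNA_Arg(CCG), 58 of 78 rose, 60 rose adjusted over the list alone (RPL7A 0.78 ± 0.08, RPL24 0.72 ± 0.08). The ribosomal protein list had a camera adjusted p of 5.46e-09, and an adjusted p of 0.671 with an estimated correlation. Among immediate early genes 15 of 25 rose and 7 fell, the same adjusted over the list alone (JUNB 1.35 ± 0.10, ZFP36 1.57 ± 0.11, but MYC -1.40 ± 0.08). The immediate early list had a camera adjusted p of 0.0496, and an adjusted p of 0.565 with an estimated correlation. Enzymes of tRNA processing and modification mostly fell: 4 of 50 rose and 31 fell, 5 rose and 31 fell adjusted over the list alone (TRMT2A -1.26 ± 0.07, POP5 -1.49 ± 0.09, but NSUN6 1.15 ± 0.07). The tRNA enzyme list had a camera adjusted p of 0.00051, and an adjusted p of 0.384 with an estimated correlation. Among mitochondrial aminoacyl-tRNA synthetases 1 of 17 rose and 9 fell, 1 rose and 10 fell adjusted over the list alone (EARS2 -1.49 ± 0.07, SARS2 -1.56 ± 0.14). The mitochondrial synthetase list had a camera adjusted p of 0.0246, and an adjusted p of 0.568 with an estimated correlation. Among the mitochondrially encoded mRNAs 12 of 13 fell, the same adjusted over the list alone (MT-CO3 -0.74 ± 0.07), and their share of all counts went from 3.42% ± 0.0900 to 2.83% ± 0.0366. The mitochondrial mRNA list had a camera adjusted p of 0.00066, and an adjusted p of 0.387 with an estimated correlation. Among the NRF2 targets 1 of 17 rose and 10 fell, 1 rose and 11 fell adjusted over the list alone (PIR -1.28 ± 0.09, the glutathione synthesis enzyme GCLC -0.80 ± 0.06). The NRF2 list had a camera adjusted p of 0.00861, and an adjusted p of 0.384 with an estimated correlation. Among the proteasome subunits 3 of 31 rose and 16 fell, the same adjusted over the list alone (PSMD11 -0.56 ± 0.05, PSMD14 -0.56 ± 0.06). The proteasome list had a camera adjusted p of 0.0496, and an adjusted p of 0.731 with an estimated correlation. RLE factors ended the calls of the proteasome list (adjusted p = 0.0666) and the immediate early list (adjusted p = 0.0512), the latter also lost with library totals (adjusted p = 0.0554) and with the replicate block (adjusted p = 0.0501). The 13 lists not called had camera adjusted p-values of 0.0704 to 0.697, such as cytosolic chaperones (6 of 30 rose and 15 fell, the same adjusted over the list alone), interferon-stimulated genes (9 of 29 rose and 16 fell, 9 rose and 17 fell adjusted over the list alone) and cholesterol synthesis (2 of 24 rose and 12 fell, the same adjusted over the list alone). The replicate block added a call of the cell cycle list (adjusted p = 0.0463).

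The largest rises with Ser-tRNA_Arg(CCG) included genes best known from other tissues. The thyroid hormone precursor TG (chromosome 8, 132866958 to 133134903) rose by 6.03 ± 0.37, from 0.148 ± 0.0198 to 9.87 ± 3.08 CPM, and the leukocyte actin-bundling protein LCP1 (chromosome 13, 46125920 to 46211871) by 4.79 ± 0.18, from 0.745 ± 0.253 to 20.8 ± 1.41 CPM. Serum albumin ALB rose by 4.14 ± 0.27 and the haematopoietic receptor FLT3 by 3.99 ± 0.27. MGAM and MGAM2, maltase-glucoamylase genes with shared sequence, so that the split of reads between them is uncertain, rose by 4.09 ± 0.22 and 4.47 ± 0.26. DNAH12, TSSK4, NUTM2B and SLC6A20 rose by 3.92 to 4.19. The list of other-cell markers was not called (4 of 13 rose and 4 fell, the same adjusted over the list alone; camera adjusted p = 0.697). The interferon-induced MX1 went from 293 to 6 counts over 3 libraries, 48.8-fold lower (95% counting interval 22.1 to 134.03), and its mean with the mc-tRNA lay below the floor. Other large falls were in B3GAT1-DT (-3.61 ± 0.34), ANKRD1 (-3.09 ± 0.30) and ALMS1-IT1 (-3.07 ± 0.25), followed by MIR222HG, ZBTB8B, NMRK2, ETV4, ANXA1 and RAPGEF3 at -2.80 to -2.35. Of the fixed stress genes HSPA1A (-1.48 ± 0.20), ATF3 (-0.87 ± 0.08) and the asparagine synthetase ASNS (-0.43 ± 0.13) fell, and CDKN1A was not called (0.18 ± 0.08, adjusted p = 0.0573). DDIT3 rose by 0.39 ± 0.14 (adjusted p = 0.024) and IFIT1 by 0.60 ± 0.19 (adjusted p = 0.00687). DDIT3 lost its call without reporter replicate 1, 2 or 3 or mc-tRNA replicate 1 or 2 (adjusted p 0.0541 to 0.0778). IFIT1 lost its call without reporter replicate 1 (adjusted p = 0.084). With no filter on low counts the adjusted p of DDIT3 was 0.058.

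With Arg-tRNA_Gln(CUG), 61 genes rose and 62 fell. Of these, 8 rises and 34 falls were at least 2-fold, and 2270 genes had an unadjusted p under 0.05. A split of the same libraries that mixed the groups called 217 genes, so the count of 123 is not above that of every other split. FMC1, which codes for a mitochondrial assembly factor (ENSG00000164898, chromosome 7, 139339457 to 139346319), rose by 4.91 ± 0.13, from 6.36 ± 0.202 to 191 ± 14.3 CPM. The gene overlaps LUC7L2, so the split of reads between them is uncertain. PIR and the haem oxygenase HMOX1, both NRF2 targets, rose by 0.64 ± 0.09 and 0.77 ± 0.16, and the growth factor receptor EGFR by 0.53 ± 0.08. CTSK (0.71 ± 0.13), UNKL (0.63 ± 0.09) and KLHL29 (0.62 ± 0.10) rose too. The calcium channel gene CALHM1 went from 292 counts over 3 libraries to 3, which is 101-fold lower (95% counting interval 34.4 to 494), and the ratio grew by over 1.5 times without mc-tRNA replicate 1. The keratin gene KRT3 (chromosome 12, 52789685 to 52796117) stood at -3.75 ± 0.34, from 2.66 ± 0.834 to 0.195 ± 0.0673 CPM, LINC00485 at -3.04 ± 0.32, MYPN at -3.01 ± 0.29 and F11-AS1 at -2.82 ± 0.23. JAZF1-AS1, C6orf163, PM20D1, LINC00858 and the histone gene H2AC6 fell as well, at -2.50 to -1.25.

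Several lists shifted slightly with Arg-tRNA_Gln(CUG), with few members called. Among cytosolic chaperones 3 of 30 rose, 7 rose adjusted over the list alone, HSPA8 by 0.38 ± 0.08, HSP90AA1 by 0.36 ± 0.08 and DNAJB1 by 0.32 ± 0.08. The chaperone list had a camera adjusted p of 1.07e-08, and an adjusted p of 0.274 with an estimated correlation. Among the NRF2 targets 2 of 17 rose, 4 rose adjusted over the list alone. The NRF2 list had a camera adjusted p of 4.95e-05, and an adjusted p of 0.148 with an estimated correlation. Among the p53 targets 1 of 22 rose, the same adjusted over the list alone, namely TP53INP1 (0.42 ± 0.09). The p53 list had a camera adjusted p of 0.000128, and an adjusted p of 0.432 with an estimated correlation. Among the proteasome subunits 1 of 31 rose, 5 rose adjusted over the list alone, namely PSMD11 (0.25 ± 0.05). The proteasome list had a camera adjusted p of 3.51e-06, and an adjusted p of 0.432 with an estimated correlation. The ER unfolded protein response and ribosomal protein lists shifted up with no member called (the same adjusted over the list alone): medians 0.11 and 0.06. The unfolded protein response list had a camera adjusted p of 4.95e-05, and an adjusted p of 0.432 with an estimated correlation. The ribosomal protein list had a camera adjusted p of 0.000654, and an adjusted p of 0.619 with an estimated correlation. Downward shifts were found for histones, of which 2 of 21 fell, the same adjusted over the list alone, namely H2AC6 (-1.25 ± 0.12) and H1-2 (-0.49 ± 0.11). The histone list had a camera adjusted p of 2.19e-06, and an adjusted p of 0.148 with an estimated correlation. Integrated stress response targets shifted down too: 1 of 36 rose and 1 fell, 1 rose and 4 fell adjusted over the list alone, GDF15 at 0.50 ± 0.12 and CTH at -0.50 ± 0.10. The integrated stress response list had a camera adjusted p of 0.0141, and an adjusted p of 0.615 with an estimated correlation. So did cytosolic synthetases (none of 23 was called, 1 fell adjusted over the list alone), mitochondrially encoded mRNAs (none of 13 was called, the same adjusted over the list alone) and tRNA enzymes (none of 50 was called, the same adjusted over the list alone). The cytosolic synthetase list had a camera adjusted p of 0.000659, and an adjusted p of 0.432 with an estimated correlation. The mitochondrial mRNA list had a camera adjusted p of 0.00261, and an adjusted p of 0.432 with an estimated correlation. The tRNA enzyme list had a camera adjusted p of 0.0476, and an adjusted p of 0.518 with an estimated correlation. The 12 lists not called had camera adjusted p-values of 0.0616 to 0.75, such as immediate early genes (2 of 25 fell, 2 rose and 5 fell adjusted over the list alone) and autophagy (1 of 22 rose, the same adjusted over the list alone). Library totals added calls of the mitochondrial synthetase and interferon lists (adjusted p = 0.0364 and 0.049).

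Other rises with Arg-tRNA_Gln(CUG) were STYK1 (1.07 ± 0.24), LINC00324 (0.99 ± 0.21) and TBX19 (0.53 ± 0.12). HSPA1A (0.47 ± 0.27), HSPA5 (0.17 ± 0.07), DDIT3 (0.02 ± 0.15), ASNS (-0.32 ± 0.13), ATF3 (-0.14 ± 0.08), IFIT1 (0.14 ± 0.13) and CDKN1A (0.20 ± 0.08) were not called (adjusted p 0.342 to 0.992), and DDIT3 changed sign with library totals (-0.01). The count of called genes was 79 without EGFP(R96Q) replicate 1, 45 without EGFP(R96Q) replicate 2 and 62 without mc-tRNA replicate 3. STYK1 lost its call without reporter replicate 2 or 3 or mc-tRNA replicate 2 (adjusted p 0.0991 to 0.191). LINC00324 lost its call without reporter replicate 1 or 2 or mc-tRNA replicate 1 or 2 (adjusted p 0.071 to 0.142). HMOX1 lost its call without reporter replicate 2 or 3 or mc-tRNA replicate 1 or 2 (adjusted p 0.0822 to 0.133). TBX19 lost its call without reporter replicate 1, 2 or 3 or mc-tRNA replicate 1, 2 or 3 (adjusted p 0.0547 to 0.185). HSP90AA1 lost its call without reporter replicate 2 or mc-tRNA replicate 2 (adjusted p 0.125 to 0.242). DNAJB1 lost its call without reporter replicate 1, 2 or 3 or mc-tRNA replicate 1, 2 or 3 (adjusted p 0.0774 to 0.252). CTH lost its call without reporter replicate 1 or 2 or mc-tRNA replicate 3 (adjusted p 0.084 to 0.0947). GDF15 lost its call without reporter replicate 1, 2 or 3 or mc-tRNA replicate 1 or 2 (adjusted p 0.0958 to 0.188). PSMD11 lost its call without reporter replicate 2 or 3 or mc-tRNA replicate 1 or 3 (adjusted p 0.0828 to 0.159). TP53INP1 lost its call without reporter replicate 1, 2 or 3 or mc-tRNA replicate 2 or 3 (adjusted p 0.0631 to 0.152). H1-2 lost its call without reporter replicate 2 or 3 or mc-tRNA replicate 1, 2 or 3 (adjusted p 0.0549 to 0.195). With only the 6 libraries compared, calls were lost for GDF15 (adjusted p = 0.0869), PSMD11 (adjusted p = 0.101), TBX19 (adjusted p = 0.16), STYK1 (adjusted p = 0.247) and HMOX1 (adjusted p = 0.317). Without the EGFP(R65) libraries they were lost for HMOX1 (adjusted p = 0.0541), HSP90AA1 (adjusted p = 0.057), TP53INP1 (adjusted p = 0.0578), GDF15 (adjusted p = 0.0683) and DNAJB1 (adjusted p = 0.0755), with no filter on low counts for PSMD11 (adjusted p = 0.0879) and with library totals for GDF15 (adjusted p = 0.0688). With library totals 38.3% of called genes were higher, against 49.6% with TMM.

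With Arg-tRNA_Cys(GCA), 6750 genes rose and 6800 fell, 2635 and 2524 of them at least 2-fold, and heat shock genes led the rises. DNAJB1, an HSP40 co-chaperone (ENSG00000132002, chromosome 19, 14514770 to 14529770), rose by 7.27 ± 0.10, from 127 ± 4.94 to 19590.0 ± 132.5 CPM. The inducible HSP70 genes HSPA6 (ENSG00000173110, chromosome 1, 161524540 to 161526910) and HSPA1A (ENSG00000204389, chromosome 6, 31815464 to 31817946) rose by 14.16 ± 0.37, from 0.468 ± 0.0794 to 8668 ± 358 CPM, and by 7.02 ± 0.18, from 1.09 ± 0.130 to 143.1 ± 3.46 CPM. HSPA1A shares sequence with HSPA1B and HSPA6 with HSPA7, so the split of reads within each pair is uncertain. The small heat shock protein CRYAB rose by 10.51 ± 0.35. Among the cytosolic chaperones 29 of 30 rose, the same adjusted over the list alone, with a median of 3.30, and with HSPA6 and HSPA7 this list went from 1.04% ± 0.0229 to 10.5% ± 0.160 of all counts. The chaperone list had a camera adjusted p of 3.2e-25, and an adjusted p of 0.0224 with an estimated correlation. Among the ER unfolded protein response genes 27 of 28 rose, the same adjusted over the list alone, with HSPA5 at 3.76 ± 0.08, HERPUD1 at 3.72 ± 0.09 and XBP1 at 2.90 ± 0.07. The unfolded protein response list had a camera adjusted p of 4.33e-18, and an adjusted p of 0.0414 with an estimated correlation.

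All integrated stress response targets rose with Arg-tRNA_Cys(GCA): 36 of 36 rose, the same adjusted over the list alone, with a median of 1.80. The integrated stress response list had a camera adjusted p of 2.68e-18, and an adjusted p of 0.0986 with an estimated correlation. Among them were the transcription factors ATF3 (3.59 ± 0.09) and DDIT3 (3.48 ± 0.15), the eIF2α phosphatase subunit PPP1R15A (3.70 ± 0.10) and ASNS (1.84 ± 0.13). Among the immediate early genes 16 of 25 rose and 2 fell, the same adjusted over the list alone (IER5 4.06 ± 0.08, DUSP1 3.78 ± 0.10). The immediate early list had a camera adjusted p of 0.000159, and an adjusted p of 0.0986 with an estimated correlation. Among the autophagy genes 18 of 22 rose and 2 fell, the same adjusted over the list alone (MAP1LC3B 2.34 ± 0.07, SQSTM1 1.74 ± 0.07). The autophagy list had a camera adjusted p of 8.22e-07, and an adjusted p of 0.0986 with an estimated correlation. Among the NF-kB genes 10 of 15 rose and 3 fell, the same adjusted over the list alone (TNFAIP3 2.48 ± 0.10, RELB 2.15 ± 0.10). The NF-kB list had a camera adjusted p of 0.00556, and an adjusted p of 0.119 with an estimated correlation. Among the cytosolic synthetases 19 of 23 rose and 3 fell, the same adjusted over the list alone (TARS1 2.17 ± 0.07, GARS1 2.16 ± 0.07). The cytosolic synthetase list had a camera adjusted p of 1.02e-06, and an adjusted p of 0.19 with an estimated correlation. Of their mitochondrial counterparts 3 of 17 rose and 12 fell, the same adjusted over the list alone (TARS2 -1.20 ± 0.06, AARS2 -1.10 ± 0.07). The mitochondrial synthetase list had a camera adjusted p of 0.000205, and an adjusted p of 0.138 with an estimated correlation. Among the mitochondrially encoded mRNAs 10 of 13 fell, the same adjusted over the list alone (MT-CO3 -0.87 ± 0.07). The mitochondrial mRNA list had a camera adjusted p of 0.00579, and an adjusted p of 0.282 with an estimated correlation.

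The TMM factors of the Arg-tRNA_Cys(GCA) libraries were 0.714 to 0.730, and library totals in place of TMM moved the median of all genes by -0.55 log2. With library totals 3143 genes rose and 12401 fell, a share of rises of 20.2% against 49.8%. The chaperone, ER unfolded protein response, integrated stress response, NF-kB, immediate early, autophagy and cytosolic synthetase lists then kept positive medians (2.75, 1.05, 1.254, 0.47, 0.38, 0.15 and 0.30). Lists with smaller rises turned negative with library totals. Among the proteasome subunits 25 of 31 rose, 27 rose adjusted over the list alone (PSMC2 1.58 ± 0.06), with a median of 0.45 against -0.09 with library totals. The proteasome list had a camera adjusted p of 1.54e-07, and an adjusted p of 0.266 with an estimated correlation. Among the ribosomal proteins 59 of 78 rose and 1 fell, 61 rose and 1 fell adjusted over the list alone (RPL17 1.54 ± 0.08), with 0.39 against -0.15. The ribosomal protein list had a camera adjusted p of 8.22e-07, and an adjusted p of 0.536 with an estimated correlation. Among the translation factors 34 of 42 rose and 5 fell, the same adjusted over the list alone (EIF2S2 1.93 ± 0.06), with 0.47 against -0.07. The translation factor list had a camera adjusted p of 9.08e-07, and an adjusted p of 0.138 with an estimated correlation. Among the ribosome quality control genes 13 of 25 rose and 4 fell, the same adjusted over the list alone (GTPBP2 2.07 ± 0.07), with 0.27 against -0.28. The ribosome quality control list had a camera adjusted p of 0.0135, and an adjusted p of 0.193 with an estimated correlation. Among the NRF2 targets 10 of 17 rose and 6 fell, the same adjusted over the list alone (the ferritin subunit FTL 1.70 ± 0.09), with 0.22 against -0.32. The NRF2 list had a camera adjusted p of 0.0404, and an adjusted p of 0.282 with an estimated correlation. Library totals ended the calls of the ribosomal protein, ribosome quality control and NRF2 lists (adjusted p = 0.146, 0.481 and 0.121). They added calls of the tRNA enzyme, cholesterol synthesis and other-cell lists (adjusted p = 0.00663, 0.0314 and 0.0115).

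Other large rises with Arg-tRNA_Cys(GCA) started from almost no counts. HSPA7 went from 3 to 7516 counts over 3 libraries, 3753-fold (95% counting interval 1284 to 18203), the desmosomal gene DSC1 from 1 to 1663, 2491-fold (447 to 98456), and TRIML2 from 3 to 458, 229-fold (77.8 to 1113). SEZ6L went from 9 to 743 counts, 124-fold (64.8 to 272) and SYT4 from 10 to 771 counts, 116-fold (62.5 to 242), and ESRP1 rose by 8.60 ± 0.26. Without EGFP(R96C) replicate 3 ESRP1 stood at 9.40, and the ratios of HSPA7, DSC1, TRIML2, SEZ6L and SYT4 also grew by over 1.5 times. The largest falls were in TYRO3P (-3.66 ± 0.24), the epidermal gene EVPL (-3.44 ± 0.26), C6orf163 (-3.14 ± 0.23), MSANTD1 (-3.11 ± 0.27) and EEF1A1-AS1 (-3.08 ± 0.26), with HOXC-AS2, LINC00304, SSPOP and DUSP5P1 at -2.79 to -2.67. RNVU1-27 stood at -2.95 ± 0.51, or at -1.91 without EGFP(R96C) replicate 2 and -3.66 without mc-tRNA replicate 2. Without the latter TYRO3P stood at -4.31. IFIT1 fell (-1.04 ± 0.15). CDKN1A rose by 0.28 ± 0.08 (adjusted p = 0.0033) but with library totals was called lower, at -0.27 (adjusted p = 0.00247). Its direction thus depended on the scaling. The call of its rise was lost without EGFP(R96C) replicate 3 (adjusted p = 0.0528) or mc-tRNA replicate 1 (adjusted p = 0.103). The 9 lists not called had camera adjusted p-values of 0.11 to 0.994, such as p53 targets (14 of 22 rose and 6 fell, the same adjusted over the list alone), the cell cycle (14 of 38 rose and 15 fell, 15 rose and 15 fell adjusted over the list alone), histones (7 of 21 rose and 5 fell, the same adjusted over the list alone) and hypoxia and glycolysis (10 of 28 rose and 11 fell, the same adjusted over the list alone), all with negative medians under library totals (-0.20, -0.46, -0.47 and -0.54).

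**Figure D3:**
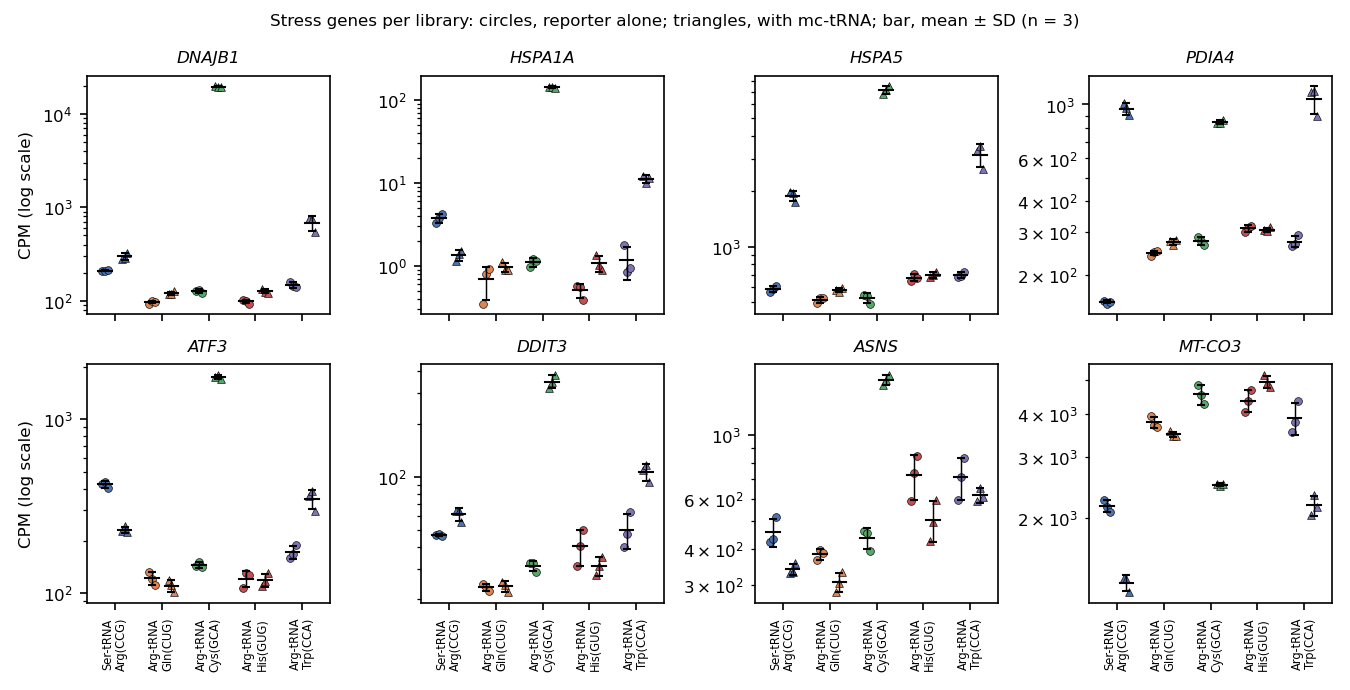
CPM on a log axis (y) of 8 stress genes in each of the 30 libraries, by mc-tRNA (x); circles are reporter alone, triangles are with the mc-tRNA, bars are mean ± SD (n = 3). DNAJB1 rose to 19590.0 CPM with Arg-tRNA_Cys(GCA) and to 681 CPM with Arg-tRNA_Trp(CCA).

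With Arg-tRNA_His(GUG), 348 genes rose and 212 fell, 80 and 20 of them at least 2-fold. FMC1 rose by 3.37 ± 0.12, from 7.27 ± 0.647 to 75.1 ± 2.11 CPM. MGAM (2.19 ± 0.26, reads shared with MGAM2), the natriuretic peptide receptor NPR3 (1.54 ± 0.19), FBXO40 (1.49 ± 0.18), PRICKLE2-AS1 (1.45 ± 0.27), FAM169A-AS1 (1.43 ± 0.26) and ABHD16B (1.23 ± 0.20) rose too. Among the cytosolic chaperones 15 of 30 rose, 23 rose adjusted over the list alone, with a median of 0.27 (HSPA8 0.53 ± 0.08, HSPH1 0.43 ± 0.08). The chaperone list had a camera adjusted p of 3.24e-20, and an adjusted p of 0.0206 with an estimated correlation. Among the integrated stress response targets 17 of 36 fell, 1 rose and 28 fell adjusted over the list alone, with a median of -0.35 (CBS -0.39 ± 0.07, SLC7A1 -0.38 ± 0.07, CHAC1 -1.15 ± 0.22). The integrated stress response list had a camera adjusted p of 1.05e-20, and an adjusted p of 0.0458 with an estimated correlation. Among the p53 targets 8 of 22 rose, 14 rose adjusted over the list alone (BTG2 0.55 ± 0.09, FDXR 0.45 ± 0.08). The p53 list had a camera adjusted p of 3.46e-13, and an adjusted p of 0.0398 with an estimated correlation. Among the mitochondrially encoded mRNAs 4 of 13 rose, 10 rose adjusted over the list alone (MT-ND1 0.46 ± 0.08). The mitochondrial mRNA list had a camera adjusted p of 5.99e-08, and an adjusted p of 0.0458 with an estimated correlation. Among the interferon-stimulated genes 1 of 29 rose and 5 fell, 1 rose and 13 fell adjusted over the list alone (IFIT1 -0.69 ± 0.13, IFIT3 -1.02 ± 0.24, but ISG20 0.75 ± 0.18). The interferon list had a camera adjusted p of 9.13e-07, and an adjusted p of 0.00462 with an estimated correlation.

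Immediate early genes and histones were called upward with Arg-tRNA_His(GUG): 2 of 25 rose, 9 rose adjusted over the list alone (FOSL1 0.89 ± 0.18) and 3 of 21 rose, 7 rose adjusted over the list alone (H1-2 0.59 ± 0.11). The immediate early list had a camera adjusted p of 1.64e-07, and an adjusted p of 0.0206 with an estimated correlation. The histone list had a camera adjusted p of 1.75e-07, and an adjusted p of 0.0438 with an estimated correlation. Among the cholesterol synthesis genes 3 of 24 rose, 9 rose adjusted over the list alone (IDI1 0.37 ± 0.08). The cholesterol synthesis list had a camera adjusted p of 0.000255, and an adjusted p of 0.181 with an estimated correlation. Among the cell cycle genes 4 of 38 rose, 6 rose adjusted over the list alone (NUSAP1 0.22 ± 0.06). The cell cycle list had a camera adjusted p of 1.79e-05, and an adjusted p of 0.275 with an estimated correlation. Among the cytosolic synthetases 1 of 23 fell, 8 fell adjusted over the list alone (LARS1 -0.22 ± 0.06). The cytosolic synthetase list had a camera adjusted p of 0.0129, and an adjusted p of 0.503 with an estimated correlation. Among the translation factors 1 of 42 rose, the same adjusted over the list alone (EIF5 0.39 ± 0.09). The translation factor list had a camera adjusted p of 0.0154, and an adjusted p of 0.479 with an estimated correlation. Proteasome subunits (none of 31 was called, the same adjusted over the list alone), ribosomal proteins (none of 78 was called, the same adjusted over the list alone) and tRNA enzymes (none of 50 was called, the same adjusted over the list alone) shifted up as lists. The proteasome list had a camera adjusted p of 3.83e-05, and an adjusted p of 0.471 with an estimated correlation. The ribosomal protein list had a camera adjusted p of 0.00113, and an adjusted p of 0.622 with an estimated correlation. The tRNA enzyme list had a camera adjusted p of 0.0392, and an adjusted p of 0.471 with an estimated correlation. Library totals ended the calls of the tRNA enzyme and translation factor lists (adjusted p = 0.0963 and 0.0588). The 9 lists not called had camera adjusted p-values of 0.0673 to 0.923, such as the ER unfolded protein response (none of 28 was called, 1 rose and 4 fell adjusted over the list alone) and hypoxia and glycolysis (1 of 28 fell, the same adjusted over the list alone).

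HSPA1A rose by 1.09 ± 0.27 with Arg-tRNA_His(GUG) and ASNS fell (-0.52 ± 0.12). HSPA5 (0.05 ± 0.07), DDIT3 (-0.37 ± 0.15), ATF3 (-0.02 ± 0.08) and CDKN1A (0.17 ± 0.08) were not called (adjusted p = 0.777, 0.191, 0.925 and 0.28). Rises of CASS4, TAS1R1 and NEB (1.249 to 1.45) and falls of ALPK2, INHBE, SULT1C2, ZMAT1, IFI44L, HEXIM2-AS1, OAS3 and SGMS1-AS1 (-1.33 to -0.87) all lost their calls without EGFP(R96H) replicate 3 and without mc-tRNA replicate 1. Calls were also lost without EGFP(R96H) replicate 1 for NEB, without replicate 2 for CASS4, NEB, ALPK2, ZMAT1 and OAS3, without mc-tRNA replicate 2 for CASS4, NEB, ALPK2, SULT1C2, ZMAT1, HEXIM2-AS1 and OAS3, and without mc-tRNA replicate 3 for IFI44L. The adjusted p-values of these losses were 0.0518 to 0.292. The count of called genes was 198 without EGFP(R96H) replicate 2, 73 without EGFP(R96H) replicate 3, 53 without mc-tRNA replicate 1 and 180 without mc-tRNA replicate 2. HSPH1 lost its call without reporter replicate 3 or mc-tRNA replicate 1 (adjusted p 0.0568 to 0.0572). SLC7A1 lost its call without mc-tRNA replicate 1 (adjusted p = 0.0562). CHAC1 lost its call without reporter replicate 3 or mc-tRNA replicate 1 (adjusted p 0.0678 to 0.0801). MT-ND1 lost its call without mc-tRNA replicate 1 (adjusted p = 0.0563). IFIT1 lost its call without mc-tRNA replicate 1 (adjusted p = 0.066). IFIT3 lost its call without reporter replicate 3 or mc-tRNA replicate 1, 2 or 3 (adjusted p 0.0552 to 0.112). ISG20 lost its call without reporter replicate 1 or 2 or mc-tRNA replicate 1 or 2 (adjusted p 0.06 to 0.144). H1-2 lost its call without mc-tRNA replicate 1 (adjusted p = 0.0765). IDI1 lost its call without reporter replicate 2 or 3 or mc-tRNA replicate 2 or 3 (adjusted p 0.0563 to 0.091). NUSAP1 lost its call without reporter replicate 1, 2 or 3 or mc-tRNA replicate 1 or 2 (adjusted p 0.0587 to 0.131). LARS1 lost its call without reporter replicate 2 or 3 or mc-tRNA replicate 1 or 2 (adjusted p 0.0924 to 0.301). EIF5 lost its call without reporter replicate 2 or 3 or mc-tRNA replicate 1 or 2 (adjusted p 0.0744 to 0.195). HSPA1A lost its call without reporter replicate 2 or 3 or mc-tRNA replicate 1 or 2 (adjusted p 0.0802 to 0.26). ASNS lost its call without reporter replicate 2 or 3 or mc-tRNA replicate 1 or 2 (adjusted p 0.0909 to 0.234). With only the 6 libraries compared, calls were lost for CHAC1 (adjusted p = 0.138), INHBE (adjusted p = 0.143) and ASNS (adjusted p = 0.206). Without the EGFP(R65) libraries they were lost for LARS1 (adjusted p = 0.0516) and HSPA1A (adjusted p = 0.054), and with no filter on low counts for NUSAP1 (adjusted p = 0.0991). With library totals 48.4% of called genes were higher, against 62.1% with TMM.

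**Figure D4:**
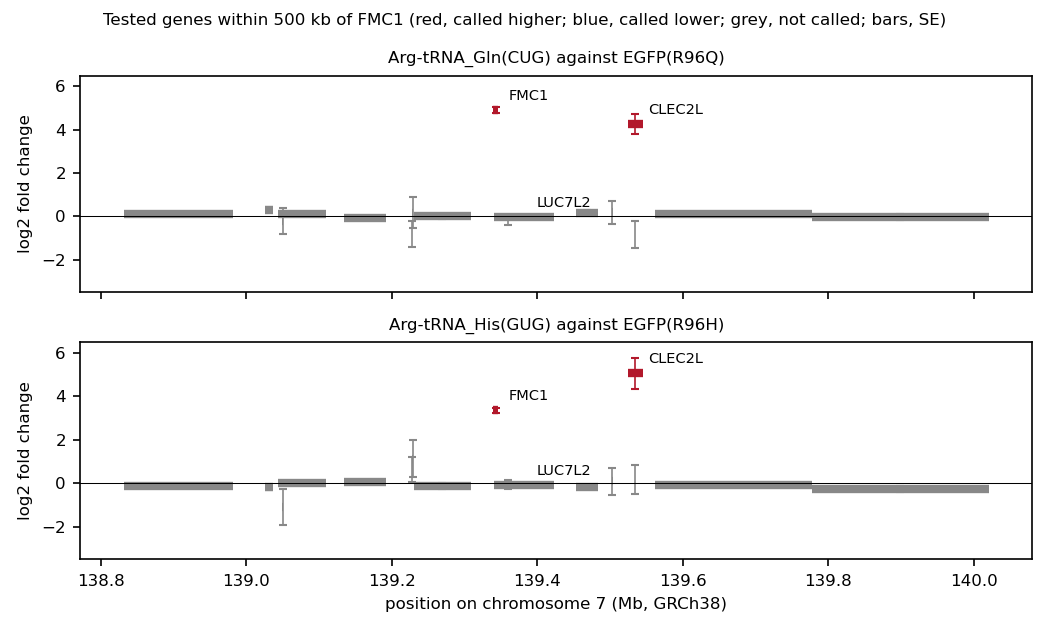
Log2 fold change (y axis, 3 against 3 libraries, bars are SE from the fit to all 30 libraries) of the tested genes within 500 kb of FMC1 by position on chromosome 7 (x axis), with Arg-tRNA_Gln(CUG) and with Arg-tRNA_His(GUG). FMC1 stood at 4.91 and 3.37, while none of the 15 other neighbours was called higher; CLEC2L, chosen after its values were seen, went from 11 to 225 counts and from 2 to 72 counts, so its fitted value rests on few counts.

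With Arg-tRNA_Trp(CCA), 4628 genes rose and 4852 fell, 778 and 905 of them at least 2-fold. All cytosolic chaperones rose: 30 of 30 rose, the same adjusted over the list alone, with a median of 1.09. The chaperone list had a camera adjusted p of 4.67e-30, and an adjusted p of 0.00509 with an estimated correlation. The co-chaperone BAG3 rose by 2.88 ± 0.09, from 44.7 ± 0.953 to 329 ± 65.5 CPM, DNAJB1 by 2.20 ± 0.08, HSPH1 by 2.16 ± 0.09 and HSPB1 by 1.75 ± 0.08. HSPA6 rose by 5.89 ± 0.28, HSPA1A by 3.23 ± 0.18, HSPA1B by 2.62 ± 0.18, CRYAB by 2.63 ± 0.29 and ZFAND2A by 2.65 ± 0.11. Among the ER unfolded protein response genes 27 of 28 rose, the same adjusted over the list alone, with a median of 1.21 (HSPA5 2.18 ± 0.07, PDIA4 1.94 ± 0.07, DERL3 2.86 ± 0.10). The unfolded protein response list had a camera adjusted p of 1.15e-30, and an adjusted p of 0.00509 with an estimated correlation. Among the autophagy genes 20 of 22 rose, the same adjusted over the list alone (WIPI1 1.34 ± 0.10, MAP1LC3B 0.77 ± 0.07). The autophagy list had a camera adjusted p of 8.35e-09, and an adjusted p of 0.04 with an estimated correlation. Among the ribosome quality control genes 15 of 25 rose and 1 fell, 16 rose and 1 fell adjusted over the list alone (the ubiquitin ligases RNF10 0.63 ± 0.06 and ZNF598 0.74 ± 0.08). The ribosome quality control list had a camera adjusted p of 9.06e-05, and an adjusted p of 0.04 with an estimated correlation. Among the mitochondrially encoded mRNAs 12 of 13 fell, the same adjusted over the list alone (MT-CO3 -0.84 ± 0.07). The mitochondrial mRNA list had a camera adjusted p of 8.35e-09, and an adjusted p of 0.04 with an estimated correlation. Among the interferon-stimulated genes 2 of 29 rose and 13 fell, the same adjusted over the list alone (IFIT1 -1.15 ± 0.15). The interferon list had a camera adjusted p of 0.00285, and an adjusted p of 0.04 with an estimated correlation.

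Among integrated stress response targets with Arg-tRNA_Trp(CCA), 20 of 36 rose and 3 fell, the same adjusted over the list alone (PPP1R15A 1.74 ± 0.09, ATF3 1.02 ± 0.08). The integrated stress response list had a camera adjusted p of 0.00104, and an adjusted p of 0.544 with an estimated correlation. Among the immediate early genes 14 of 25 rose and 4 fell, the same adjusted over the list alone (IER5 0.90 ± 0.08, but KLF10 -0.96 ± 0.07). The immediate early list had a camera adjusted p of 0.0066, and an adjusted p of 0.225 with an estimated correlation. Among the p53 targets 10 of 22 rose and 2 fell, 11 rose and 2 fell adjusted over the list alone (BTG2 1.10 ± 0.09, TNFRSF10B 0.95 ± 0.06). The p53 list had a camera adjusted p of 0.0178, and an adjusted p of 0.544 with an estimated correlation. Among the proteasome subunits 21 of 31 rose, 22 rose adjusted over the list alone (PSMD6 0.74 ± 0.06). The proteasome list had a camera adjusted p of 8.26e-08, and an adjusted p of 0.334 with an estimated correlation. Among the translation factors 25 of 42 rose and 2 fell, the same adjusted over the list alone (ETF1 0.63 ± 0.06). The translation factor list had a camera adjusted p of 2.68e-05, and an adjusted p of 0.225 with an estimated correlation. Among the cell cycle genes 22 of 38 rose and 3 fell, the same adjusted over the list alone (CDC6 1.08 ± 0.08). The cell cycle list had a camera adjusted p of 0.000139, and an adjusted p of 0.334 with an estimated correlation. Among the ribosomal proteins 24 of 78 rose, 20 rose adjusted over the list alone (RPL17 1.01 ± 0.08). The ribosomal protein list had a camera adjusted p of 0.000357, and an adjusted p of 0.678 with an estimated correlation. Among the mitochondrial synthetases 2 of 17 rose and 9 fell, 3 rose and 9 fell adjusted over the list alone (CARS2 -0.38 ± 0.07). The mitochondrial synthetase list had a camera adjusted p of 0.0205, and an adjusted p of 0.406 with an estimated correlation. The 9 lists not called had camera adjusted p-values of 0.0659 to 0.968. Of these, RNA polymerase III factors (10 of 22 rose and 5 fell, the same adjusted over the list alone), cytosolic synthetases (9 of 23 rose and 2 fell, the same adjusted over the list alone), tRNA enzymes (16 of 50 rose and 12 fell, 17 rose and 12 fell adjusted over the list alone), NF-kB genes (3 of 15 rose and 2 fell, the same adjusted over the list alone) and NRF2 targets (5 of 17 rose and 7 fell, the same adjusted over the list alone) changed the sign of their median with library totals (-0.02, -0.04, -0.11, -0.12 and -0.10).

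DDIT3 rose by 1.10 ± 0.14 with Arg-tRNA_Trp(CCA), and ASNS (-0.21 ± 0.12, adjusted p = 0.184) and CDKN1A (0.15 ± 0.08, adjusted p = 0.128) were not called. SDCBP2 and the pseudogene HSPA5P1 rose by 2.80 ± 0.13 and 2.91 ± 0.30. The potassium channel gene KCNT1 went from 5 to 506 counts over 3 libraries, 111-fold (95% counting interval 47.4 to 345). Its rise rested on mc-tRNA replicate 3 (11.3 CPM against 0.125 and 0.130) and its call was lost without it (adjusted p = 0.468) and with limma voom (adjusted p = 0.26). The largest falls were in EVPL (-3.94 ± 0.33), IFNA22P (-3.35 ± 0.35), TYRO3P (-2.97 ± 0.23), MYPN (-2.92 ± 0.33), TNRC18P1 (-2.88 ± 0.15) and F11-AS1 (-2.78 ± 0.26), followed by LINC00304, EEF1A1-AS1, FLACC1 and RTEL1P1 at -2.76 to -2.64. Library totals added a call of the histone list (adjusted p = 0.019), moved the median of all genes by -0.13 log2 and moved the share of rises among called genes from 48.8% to 31.4%.

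**Figure D5:**
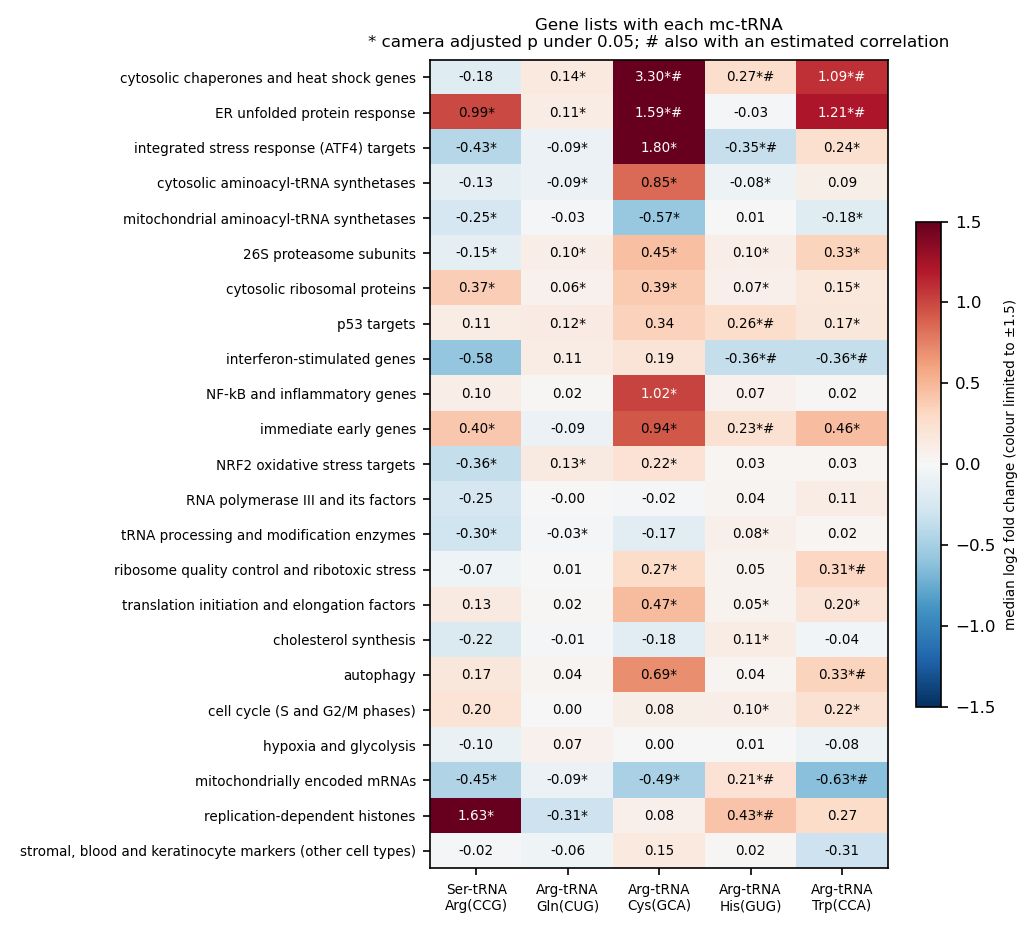
Median log2 fold change of 23 gene lists (y axis) with each mc-tRNA (x axis); an asterisk marks a camera adjusted p under 0.05, a hash sign one under 0.05 also with an estimated correlation. Chaperones reached 3.30 with Arg-tRNA_Cys(GCA); with library totals in place of TMM the Arg-tRNA_Cys(GCA) medians of the proteasome, ribosomal protein, p53, interferon, NRF2, ribosome quality control, translation factor, cell cycle, hypoxia, histone and other-cell lists turned negative, as did those of 5 lists with Arg-tRNA_Trp(CCA), none of them called.

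On average over the 5 mc-tRNAs, 6301 genes rose and 6729 fell, 460 and 272 of them at least 2-fold. Chaperones and ER genes led: 30 of 30 rose, the same adjusted over the list alone (DNAJB1 2.13 ± 0.04, BAG3 1.95 ± 0.04) and 27 of 28 rose, the same adjusted over the list alone (HSPA5 1.57 ± 0.03, HERPUD1 1.44 ± 0.04). The mean combines unlike effects. From Ser-tRNA_Arg(CCG) to Arg-tRNA_Trp(CCA), in the order given above, DNAJB1 rose by 0.52, 0.32, 7.27, 0.36 and 2.20. With Ser-tRNA_Arg(CCG) more chaperone genes fell than rose, HSPA1A among those that fell. These falls started from a higher level. With HSPA6 and HSPA7 the chaperone list took 1.59% of all counts with EGFP(R65) alone and 1.43% with Ser-tRNA_Arg(CCG). With the other reporters alone it took 0.992% to 1.21%. The chaperone list had a camera adjusted p of 4.98e-24, and an adjusted p of 0.0139 with an estimated correlation. The unfolded protein response list had a camera adjusted p of 3.18e-23, and an adjusted p of 0.0139 with an estimated correlation. HSPA6 (4.56 ± 0.26), FMC1 (2.02 ± 0.06), ALB (1.94 ± 0.17), NPR3 (1.92 ± 0.07), ZFAND2A (1.91 ± 0.05), APOL6, NHLH1 and DNAJB4 were among the largest rises. KRT3 (-2.40 ± 0.18), MYPN (-1.95 ± 0.14), C6orf163 (-1.66 ± 0.10) and PM20D1 (-1.60 ± 0.13) were among the largest falls, with LINC00858, SPAG8, LINC00173 and TIAF1 at -1.44 to -1.07. LINC00485 and F11-AS1 also passed the test, but LINC00485 had 3 counts over the libraries with Arg-tRNA_Cys(GCA), and with Ser-tRNA_Arg(CCG) F11-AS1 stood at 0 CPM against 0.0452 CPM, both below the floor. HSPA1A (2.07 ± 0.10), DDIT3 (0.92 ± 0.07), ATF3 (0.71 ± 0.04) and CDKN1A (0.20 ± 0.04) rose and IFIT1 fell (-0.43 ± 0.07), while ASNS was not called (0.07 ± 0.06, adjusted p = 0.289) and stood at -0.08 with library totals, which also ended the call of CDKN1A (adjusted p = 0.24).

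The mean effect called 16 further lists, none of which held with an estimated correlation (adjusted p 0.0737 to 0.44). Rises prevailed among ribosomal proteins (72 of 78 rose, the same adjusted over the list alone), autophagy genes (19 of 22 rose, 20 rose adjusted over the list alone), translation factors (32 of 42 rose and 2 fell, 34 rose and 3 fell adjusted over the list alone), proteasome subunits (25 of 31 rose, the same adjusted over the list alone), immediate early genes (19 of 25 rose and 3 fell, 20 rose and 3 fell adjusted over the list alone) and integrated stress response targets (25 of 36 rose and 2 fell, the same adjusted over the list alone). Of the latter, more fell than rose with Ser-tRNA_Arg(CCG) and with Arg-tRNA_His(GUG), so their mean is not a shared rise. Falls prevailed among mitochondrially encoded mRNAs (12 of 13 fell, the same adjusted over the list alone), mitochondrial synthetases (1 of 17 rose and 13 fell, the same adjusted over the list alone), interferon-stimulated genes (5 of 29 rose and 17 fell, the same adjusted over the list alone) and tRNA enzymes (11 of 50 rose and 25 fell, the same adjusted over the list alone). Library totals moved the median of all genes by -0.15 log2 and the share of rises from 48.4% to 24.9%. They turned the medians of the cytosolic synthetase and cell cycle lists from 0.10 and 0.12 to -0.06 and -0.03. They also ended the calls of these lists (adjusted p = 0.34 and 0.397), of interferon-stimulated genes (0.149, and 0.0503 with the replicate block) and of ribosome quality control (0.123). The median and the direction of the camera test differed in sign only in lists not called: other-cell markers with Ser-tRNA_Arg(CCG), NF-kB genes and RNA polymerase III factors with Arg-tRNA_Gln(CUG), the cell cycle and hypoxia with Arg-tRNA_Cys(GCA), hypoxia with Arg-tRNA_His(GUG), and RNA polymerase III factors in the mean.

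The effect of the mc-tRNA differed among the 5 reporters for 16174 genes (F-test on the differences of the effects). Each reporter had its own mc-tRNA, so a difference between mc-tRNAs and one between reporters cannot be told apart. Without the EGFP(R65) libraries, an alternative chosen after seeing the data, the remaining effects differed for 12761 genes. In the F-test over all 30 libraries, the 10 genes with the smallest p were DNAJB1 (adjusted p = 8.37e-32), DEDD2, CACYBP, HSPH1, HSPD1, HSPB1, HSP90AA1, BAG3, BCAS2 and CLU (2.87e-26), and 7 of them are on the chaperone list. Each rose most with Arg-tRNA_Cys(GCA), by 2.87 ± 0.06 for BCAS2 to 7.27 ± 0.10 for DNAJB1, and next with Arg-tRNA_Trp(CCA), by 0.81 ± 0.06 for BCAS2 to 2.88 ± 0.09 for BAG3. With Ser-tRNA_Arg(CCG) CACYBP (-0.66 ± 0.06) and HSPH1 (-0.28 ± 0.08) fell. The chaperone list differed in all 10 pairs of effects, and in 7 with an estimated correlation; it rose more with Arg-tRNA_Cys(GCA) than with Arg-tRNA_Trp(CCA) (adjusted p = 2.49e-25, and 0.0216 with an estimated correlation). The ER unfolded protein response list differed in 9 pairs and in 5 with an estimated correlation, the exception among the former being Ser-tRNA_Arg(CCG) against Arg-tRNA_Trp(CCA) (adjusted p = 0.0807).

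Arg-tRNA_Cys(GCA) and Arg-tRNA_Trp(CCA) shared 2977 rises, where independent calls would give 1400, and 2876 falls, where they would give 1478, while 1296 genes went in opposite directions. Across genes their log2 changes had a Pearson correlation of 0.461, against 0.0786 between Ser-tRNA_Arg(CCG) and Arg-tRNA_Cys(GCA); genes are not independent replicates. The effects of Arg-tRNA_Gln(CUG) and Arg-tRNA_His(GUG) differed for 181 genes and those of Ser-tRNA_Arg(CCG) and Arg-tRNA_Cys(GCA) for 12616, the fewest and the most of the 10 pairs. FMC1 differed among the effects (adjusted p = 1.16e-19): it also rose with Arg-tRNA_Cys(GCA) (1.19 ± 0.12) and Arg-tRNA_Trp(CCA) (0.66 ± 0.13), and stood at 0.00 ± 0.18 with Ser-tRNA_Arg(CCG) (adjusted p = 1).

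Without mc-tRNA, 17598 genes differed among the 5 reporters. In the 10 genes with the smallest p the EGFP(R65) group stood above the other 4: SSC4D (chromosome 7, 76389334 to 76409695) with 282 ± 15.2 CPM against 0.617 to 1.16, PAPLN with 221 ± 13.8 CPM against 0.443 to 0.906, DIPK1B with 1823 ± 54.8 CPM against 37.5 to 49.5, CCDC85C with 2584 ± 199 CPM against 45.8 to 55.3 and ZBED4 with 1309 ± 92.4 CPM against 71.1 to 79.0. The bromodomain gene BRD3 had 1131 ± 16.7 CPM against 61.3 to 71.0, TMEM30BP1 138.6 ± 9.77 CPM against 0.281 to 0.545, COL13A1 229 ± 5.94 CPM against 4.30 to 7.15, TNRC18P1 204 ± 13.5 CPM against 2.96 to 8.96 and SCN11A 80.9 ± 0.200 CPM against 0.742 to 1.15. Without the EGFP(R65) libraries 11776 genes differed among the other 4 reporters.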

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

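The tests of the 3 patterns weighed in this part were chosen after the results were seen; the tests of differences between effects were planned. The effect of the mc-tRNA differed among the 5 reporters for 16174 genes, by an F-test on the differences. Each reporter had its own mc-tRNA, so a difference between mc-tRNAs and one between reporters cannot be told apart. For the genes below the test of a difference passed, and the value is the range of the 5 log2 fold changes, highest minus lowest. Among heat shock genes the ranges were HSPA6 14.04, CRYAB 10.92, HSPA1A 8.50, DNAJB1 6.95, HSPH1 6.09, BAG3 5.51, HSPB1 4.62, HSP90AA1 4.61, CACYBP 4.17, HSPD1 3.39 and HSPA8 2.65. Among ER stress, integrated stress response and autophagy genes they were HSPA5 3.71, HERPUD1 3.97, DERL3 3.17, PDIA4 2.66, CHAC1 5.19, ATF3 4.46, DDIT3 3.85, PPP1R15A 3.74, ASNS 2.35, MAP1LC3B 2.23, ZFAND2A 5.93 and UFD1 0.94, the last chosen after its values were seen. Among immediate early, p53, NRF2 and interferon genes they were IER5 4.001, DUSP1 3.87, BTG2 0.96, PIR 2.36 and IFIT1 1.75, and for histone, synthetase, proteasome, ribosomal and mitochondrial genes H1-2 2.87, AARS2 1.06, PSMD11 1.02, RPL17 1.61, MT-CO3 1.05 and MT-ATP6 0.91. For other named genes they were MGAM 5.48, FMC1 4.91, EVPL 4.65, CLU 4.29, DEDD2 4.07, ALB 3.38, TYRO3P 3.71, KRT3 3.21, BCAS2 3.10, C6orf163 2.65, MYPN 2.28, LINC00485 4.38, NPR3 2.61, PM20D1 2.002, LINC00304 3.73, EEF1A1-AS1 3.92, LINC00858 1.17 and F11-AS1 2.64, where the lower end for F11-AS1 comes from Ser-tRNA_Arg(CCG), with both groups below the floor, and for LINC00485 from 3 counts with Arg-tRNA_Cys(GCA).

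Whole lists also differed between effects. Of the 10 pairs of effects, the chaperone list differed in 10, the ER unfolded protein response, integrated stress response and proteasome lists in 9, 9 and 9, and cytosolic synthetases, ribosomal proteins, immediate early genes and mitochondrially encoded mRNAs in 7, 7, 7 and 7. NRF2 targets, tRNA enzymes, ribosome quality control, translation factors, autophagy and histones differed in 6, 6, 6, 6, 6 and 6 pairs. Mitochondrial synthetases differed in 5, NF-kB and cell cycle genes in 4 and 4, interferon-stimulated genes in 3, cholesterol synthesis in 2, and p53 targets and RNA polymerase III factors in 1 and 1. With an estimated correlation, differences remained in 7 pairs for chaperones, 5 for the ER unfolded protein response, 2 for interferon-stimulated genes, and 1 each for immediate early genes, mitochondrially encoded mRNAs and histones. No pair remained for the other lists, the integrated stress response, proteasome, cytosolic synthetase and ribosomal protein lists included. Outside the comparisons, ERCC sequences had up to 106 counts in a library, all of it in EGFP(R96) libraries, while the 6 EGFP(R65) libraries had 0.

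The first pattern is the 34 genes at least 2-fold lower with Arg-tRNA_Gln(CUG). Of these, 28 were also called lower with Arg-tRNA_Trp(CCA), 22 with Arg-tRNA_Cys(GCA), 18 with Ser-tRNA_Arg(CCG) and 10 with Arg-tRNA_His(GUG), where 7.39, 10.4, 10.4 and 0.323 would be if calls were independent. Reads carried over with the spike-in stay open: ERCC-00014, not tested, had means of 70.7 and 16.7 counts without and with the mc-tRNA for EGFP(R96Q), 45.3 and 14.3 for EGFP(R96C), 14 and 4.33 for EGFP(R96H) and 37.3 and 11.7 for EGFP(R96W). All ERCC sequences together had means of 94 and 38, 70 and 29.3, 21 and 13.3, and 46 and 29.3 counts, in the same order. ERCC-00014 thus made up most ERCC counts of these reporters alone, and why 1 sequence prevailed was not tested. In the EGFP(R65) reporter-only libraries, with 0 ERCC counts, 17 of the 34 stood at 1 CPM or more and the others below, and other differences of EGFP(R65) keep this from deciding. Reads from 1 source such as the plasmid cannot be told apart from a response to the mc-tRNA. With 1 source in a fixed ratio, no member would be higher where the others fall. With Arg-tRNA_Cys(GCA), 22 of the 34 were called lower and 5 higher. The bar for arguing against 1 source was more than the 10.3 that independent calls would give, which the number did not reach. The plasmid sequence was not at hand.

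The second pattern is FMC1 and CLEC2L, whose starts lie 184 kb apart on chromosome 7 and which rose with both Arg-tRNA_Gln(CUG) and Arg-tRNA_His(GUG). CLEC2L, chosen after its values were seen, went from 11 to 225 counts with Arg-tRNA_Gln(CUG), 19.6-fold (95% counting interval 10.8 to 39.9), and from 2 to 72 with Arg-tRNA_His(GUG), 40.5-fold (10.8 to 341); the pair moved apart with Ser-tRNA_Arg(CCG), CLEC2L at 0.465-fold (0.402 to 0.536) and FMC1 at 0.00 log2, and CLEC2L stood at 0.999-fold (0.293 to 3.14) with Arg-tRNA_Cys(GCA) and 3.85-fold (0.734 to 38.0) with Arg-tRNA_Trp(CCA), where FMC1 rose by 1.19 and 0.66. A gain of the whole segment is argued against, since the higher of the medians of the 15 other tested genes within 500 kb was 0.00926 log2 and 0 of them were called higher. Reads of the overlapping LUC7L2 are argued against by its log2 change of -0.0366 with Arg-tRNA_Gln(CUG), and whether the genes lie close by chance was not tested. Plasmid sequence that maps to both genes and a response of the genes cannot be told apart for the 29371 FMC1 counts with Arg-tRNA_Gln(CUG), as the plasmid sequence was not at hand.

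The third pattern is the rise of ALB, TG, LCP1 and FLT3 with Ser-tRNA_Arg(CCG), genes best known from liver, thyroid and blood. RNA from hepatocytes is argued against: with ALB at 1203 counts over 3 libraries, the other 9 hepatocyte markers had a median of 4. RNA from thyroid cells is argued against by a median of 4 for 3 markers beside 1271 for TG, and RNA from blood cells by a median of 12.5 for 4 markers beside 2663 for LCP1 and 1220 for FLT3. Whether the sort for mCherry-positive cells removed such cells was not tested, and a sort cannot remove RNA that entered later. What stays open, untested, is a direct response to Ser-tRNA_Arg(CCG) or reads from a source outside these marker lists.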

How the results depend on the processing

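Library totals alone and the 24 EGFP(R96) libraries alone were chosen after seeing the data; the other alternatives were planned. Counts for Ser-tRNA_Arg(CCG), Arg-tRNA_Cys(GCA), Arg-tRNA_Trp(CCA), the mean and both F-tests stayed within 1.5 times the reported count under each alternative run; without the EGFP(R65) libraries 11776 genes differed among the reporters. For Arg-tRNA_Gln(CUG) the count of 123 became 196 with no filter on low counts, 231 with the replicate block, 311 with limma voom, 244 with DESeq2, 66 with only the 6 libraries compared and 40 at an adjusted p under 0.01. For Arg-tRNA_His(GUG) the count of 560 became 1124 with the replicate block, 3285 with limma voom, 896 with DESeq2, 1911 with only the 6 libraries compared, 369 with only the 24 EGFP(R96) libraries and 123 at an adjusted p under 0.01. The stricter threshold calls fewer genes by construction; for the other settings the cause was not tested. Leaving out 1 library gave 11637 to 12354 genes for Ser-tRNA_Arg(CCG), 45 to 93 for Arg-tRNA_Gln(CUG), 12688 to 13140 for Arg-tRNA_Cys(GCA), 53 to 636 for Arg-tRNA_His(GUG), 8112 to 8945 for Arg-tRNA_Trp(CCA), 12778 to 13123 for the mean, 15777 to 16324 for differing effects and 16888 to 17865 for the reporters. The libraries that moved a count by over 1.5 times were EGFP(R96Q) replicates 1 (79) and 2 (45), replicate 3 with Arg-tRNA_Gln(CUG) (62), EGFP(R96H) replicates 2 (198) and 3 (73), and replicates 1 (53) and 2 (180) with Arg-tRNA_His(GUG).

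Changes of sign were found in 4 gene results, and the cause was not tested. DDIT3 with Arg-tRNA_Gln(CUG), not called, stood at -0.00654 with library totals, at -0.00250 with limma voom and at -0.0258 to 0.0683 when 1 library was left out. ATF3 with Arg-tRNA_His(GUG), not called, stood at -0.112 to 0.0294 when 1 library was left out. With library totals CDKN1A with Arg-tRNA_Cys(GCA) was called lower, at -0.27 (adjusted p = 0.00247), and ASNS in the mean, not called, stood at -0.0789. Of the list results, 64 lost their call with an estimated correlation, and fry ended 14 calls and added 22. Library totals ended 10 and added 6, RLE factors ended 2, and the replicate block ended 2 and added 1. The lists were not retested with a library left out. Whether list calls rest on 1 library, those for Arg-tRNA_His(GUG) included, was thus not tested. Depth limits values from groups at or under the floor: MX1 with Ser-tRNA_Arg(CCG), CALHM1 with Arg-tRNA_Gln(CUG), HSPA7, DSC1, TRIML2, SEZ6L and SYT4 with Arg-tRNA_Cys(GCA) and KCNT1 with Arg-tRNA_Trp(CCA) are given as count ratios with intervals.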

Other observations

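The codon test and the splits below were planned; the genes called in all 5 comparisons were picked after their values were seen. In all, 8 genes were called in all 5 comparisons, 5 of them with the same sign, and 3624 in none. DNAJB1 rose in all 5, as did UFD1, which codes for an adaptor that hands ubiquitylated ER proteins to the proteasome (log2 changes 0.45, 0.36, 1.20, 0.26, 1.12, from Ser-tRNA_Arg(CCG) to Arg-tRNA_Trp(CCA) in the order given above). KRT3 (-0.54, -3.75, -2.86, -1.96, -2.88) and LINC00858 (-1.42, -1.54, -1.77, -0.66, -1.82) fell in all 5; F11-AS1 carried the same sign, with both groups below the floor for Ser-tRNA_Arg(CCG). GADD45B (0.64, -0.46, 2.59, 0.31, 0.46), MTATP6P1 (-0.56, -0.36, -0.59, 0.31, -0.62) and IRS3P (-1.18, -3.91, 1.24, -2.02, -1.87) were called in all 5 with mixed signs. MTATP6P1 is by its symbol a pseudogene of MT-ATP6, so the split of reads between them is uncertain. Some calls lay close to the threshold, as for DNAJB1 with Arg-tRNA_Gln(CUG) (adjusted p = 0.0465), and for GADD45B (adjusted p = 0.0499), KRT3 (0.0471) and LINC00858 (0.0451) with Arg-tRNA_His(GUG). The call of DNAJB1 with Arg-tRNA_Gln(CUG) was lost without any 1 of the 6 libraries (adjusted p 0.0774 to 0.252).

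A hypothesis was that mRNAs rich in the codon an mc-tRNA reads fall most with that mc-tRNA. Over 11520 genes, the Spearman correlation of codon share with log2 change in the own comparison was 0.03 for CGG, 0.04 for CAG, -0.08 for the cysteine codons, -0.05 for the histidine codons and -0.09 for TGG. It was the lowest of the 5 comparisons for 2 of the 5 codon families, cysteine and histidine, where 4 were needed for the hypothesis and at most 1 against it, so the test left it undecided. Correlations are across genes, which are not independent replicates.

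Other splits of the same libraries were also tested. For the mean effect 1 of 40 splits, the real one, called as many as 13030 genes and the highest other called 4422. For differing effects the real split also called the most (16174 against 6094, 1 of 40). The splits for the mean and for differing effects shuffled libraries within each reporter, so they test for any mc-tRNA effect. A large effect of 1 mc-tRNA could give both results. They cannot decide whether the effects share a mean change or whether they differ. Among the reporters without mc-tRNA the real split called the most too (17598 against 11912, 1 of 40), a share under 0.05. For single comparisons the 10 splits are too few for a share under 0.05. The real split and the highest other called 12790 and 0 genes for Ser-tRNA_Arg(CCG), 13550 and 123 for Arg-tRNA_Cys(GCA), 560 and 0 for Arg-tRNA_His(GUG) and 9480 and 0 for Arg-tRNA_Trp(CCA). For Arg-tRNA_Gln(CUG) they called 123 and 217, the latter with EGFP(R96Q) replicates 1 and 2 and mc-tRNA replicate 1 set against the others.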
